A study of Homo sapiens with 28 samples.

How the data were processed

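Total RNA of VCaP and LNCaP cells was hybridised to 2-colour Agilent expression arrays of 45015 spots, 23 physical arrays in 28 scans. Reverse transcription was primed with an oligo-dT primer, per the labels' protocols. The deposited scanner files hold, per the file headers, median pixel intensity of each spot and of its local background in the green (Cy3) and red (Cy5) channels. They also hold a log10 ratio of red over green after Agilent Feature Extraction background subtraction, spatial detrending and dye normalization, per the file headers. The headers name Feature Extraction 9.5.1.1 and 11.0.1.1, whereas the submitters' processing notes name 8.5.1.1. The authors' processed values, deposited as log2 ratios of 41093 probes in 28 columns, were set against the scanner values. Each column ran as androgen over ethanol with a median of -0.00739 to 0.0143, a correlation of 0.981 to 0.999 and a slope of 1.05 to 1.17 on the loess log2 ratios. Their centring method and scaling remain unknown.

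Groups, dyes and channels were taken from the labels. The androgen-treated RNA was labelled with Cy3 in the VCaP siRNA and shRNA experiments and with Cy5 in the drug and LNCaP experiments. No experiment held a dye swap, so gene-specific dye bias remains in androgen responses and cancels in knockdown and drug effects. LNCaP arrays were scanned 2 times, and both scans were averaged as 1 array. The lowest correlation between 2 arrays over all genes was 0.0135, so no array opposed the others in direction. Arrays of 1 group correlated at 0.804 to 0.991 and scans of 1 array at 0.922 to 0.982. The number of arrays limits the precision of every value.

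The deposited median intensities were background corrected with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 under R 4.3.3, with the data.table package at 1.17.8. Control spots had weight 0 in loess and were then left out, 1639 per array. Spots with an outlier mark, 79 to 302 per scan, were left out, and saturated spots, at most 18 per scan, were kept. Ratios were turned to androgen over ethanol, and spots of 1 probe were averaged. Of 41000 probes 27745 were named from the reference table of RefSeq genes, 23958 by accession, 1032 by synonym and 2755 by current symbol, giving 17843 genes. The other 13255 were tested probe by probe. A gene was represented by its brightest probe on average, provided that the gene was well above background in either channel on at least 2 arrays of its experiment. Outside the contrasts of the LNCaP and MLL1 hairpins, a further probe of opposite sign existed for 16.4% to 33.7% of called genes with several probes. Ranges over probes are given for named genes where they disagree.

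Each experiment was fitted on its own with 1 mean per group (lmFit and eBayes), leaving 5 residual degrees of freedom for siRNA and 2 each for the drug, LNCaP and VCaP shRNA experiments. All p-values of single genes are limma's with Benjamini-Hochberg adjustment at 0.05 over all genes tested. The 12 contrasts were the androgen response of each control group, each knockdown or drug effect, and the difference between the ASH2L siRNAs. Where 1 control array stood alone, it was assumed to vary like the hairpin arrays. The 2 hairpins of a target were taken as replicates. For a gene not well above background on all arrays of a group, an "at least N-fold" bound compared the bright group's mean with the dim group's mean of the higher of the array's lowest signal well above background and the probe's own signal. These bounds used normalized single-channel log2 values after loess and Aquantile and are open to dye bias.

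Tests, groups, alternatives, the rule for named genes and 13 gene lists were fixed before the data were examined. The lists held androgen-induced and androgen-repressed genes, MLL complex subunits, MLL and menin targets, proliferation, unfolded protein response and ATF4 targets, interferon, sterol and lipid synthesis, neuroendocrine, luminal, mesenchymal, stromal and basal, p53 target, and MYC and ribosome biogenesis genes. They were tested with camera at a preset correlation of 0.01 and adjusted over the 13 lists. With an estimated correlation, 1 of the 65 list calls held, the fall of proliferation genes with R1881 on the non-targeting arrays. Median, mean and test differed in sign only for lists that did not pass. The text names ASH2L, MEN1, KMT2A, ERG, KLK3, TMPRSS2 and FKBP5 in every experiment, up to 4 members of each list with the smallest adjusted p, and genes from the 10 largest rises and 10 largest falls that passed with 1 sign on every test array. Some genes that the rule selects are not reported here. Where under 3 passed, the 10 genes with the smallest p would have been named. A heat shock and immediate early list was written after the data had been seen.

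Slide and scan day were treated as batches, as a block, as a random block and within batches, where a batch held over 1 group. The slide correlation in the siRNA experiment was -0.106. The fit was tested on simulated data with 200 changed genes per contrast. Changes of 1 were recovered in 71.6% of genes for BD136, 25.4% and 26.9% for the LNCaP ASH2L and MEN1 hairpins, and 26.9% and 32.8% for the VCaP ASH2L and MLL1 hairpins. Alternatives were no background correction, median centring, the Feature Extraction ratio, the authors' processed values, other filters, the mean over probes, a joint fit of all arrays, single scans, batch and replicate blocks, leaving out each array and an estimated correlation. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Genomic coordinates of probes served only to find those nearest the 3' and 5' ends of a gene.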

Results

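Gene expression was measured in 2 human prostate cancer cell lines, VCaP and LNCaP, on 23 physical 2-colour arrays. VCaP carries a fusion that places ERG under the androgen-responsive TMPRSS2 promoter. On every array 1 channel held RNA of cells given an androgen, either the synthetic R1881 or dihydrotestosterone (DHT). The other channel held RNA of control cells given ethanol vehicle. The androgen-treated cells carried a control reagent, a knockdown of a subunit of the MLL histone methyltransferase complex, or the compound BD136. The knockdowns targeted ASH2L, menin (encoded by MEN1) or MLL1 (encoded by KMT2A). The design asks how loss of these subunits, or the compound, alters expression in androgen-treated cells.

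The arrays fall into 12 groups in 4 experiments. The VCaP siRNA experiment had 2 arrays with non-targeting siRNA and 3 with each of 2 ASH2L siRNAs, all with R1881. The VCaP drug experiment had 2 arrays with a control compound and 2 with BD136, all with DHT. The LNCaP shRNA experiment, at 12 h with DHT, had 1 array of the empty vector GIPZ and 2 each of ASH2L and MEN1 hairpins. Each of these 5 arrays was scanned 2 times and counted once. The VCaP shRNA experiment, at 24 h, had 1 GIPZ array and 2 ASH2L hairpin arrays with R1881, and 1 GIPZ array and 2 MLL1 hairpin arrays with DHT. No dose is given in the labels. Between 46.8% and 80.9% of spots were well above background in a channel. The labels do not say whether arrays of a group came from separate cultures, so p-values measure only the spread between these arrays.

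Values below are log2 differences ± standard errors from limma unless stated otherwise, and "rose" and "fell" mark an adjusted p under 0.05. An androgen response compares the androgen channel with the ethanol channel of the control arrays. A knockdown or drug effect compares the test RNA of those arrays with that of the control arrays, all with androgen, because the ethanol channel held control cells on every array. No array held knockdown or BD136 cells without androgen, so an effect on basal expression and one on the androgen response cannot be separated here. Each list's adjusted p comes from camera with a preset correlation over 13 lists.

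The targeted transcripts were examined first. As log2 androgen over ethanol, ASH2L stood at -0.80, -0.80 and -0.82 with siRNA 1 and at -1.61, -1.66 and -1.32 with siRNA 2. The non-targeting arrays read -0.08 and -0.20, and ASH2L fell over both siRNAs (-1.03 ± 0.092, adjusted p = 6.67e-06). The ASH2L hairpins gave -2.46 and -2.39 in VCaP against -0.09 on the GIPZ array, a fall (-2.33 ± 0.13, adjusted p = 1.47e-05). In LNCaP they gave -1.61 and -1.49 against 0.04, which did not pass with 1 control array (-1.59 ± 0.11, adjusted p = 0.102). MEN1 stood at -0.33 and -0.60 with its hairpins in LNCaP against -0.03 (-0.44 ± 0.14, adjusted p = 0.274). KMT2A stood at -1.04 and -0.95 with the MLL1 hairpins against -0.41 (-0.59 ± 0.13, adjusted p = 0.098). With BD136, ASH2L (-0.10 ± 0.066), MEN1 (0.013 ± 0.068) and KMT2A (-0.038 ± 0.068, probes -0.038 to 0.12) did not pass. Each targeted transcript was lower than its control on every array aimed at it, and the ASH2L falls in VCaP passed the test.

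**Figure D1:**
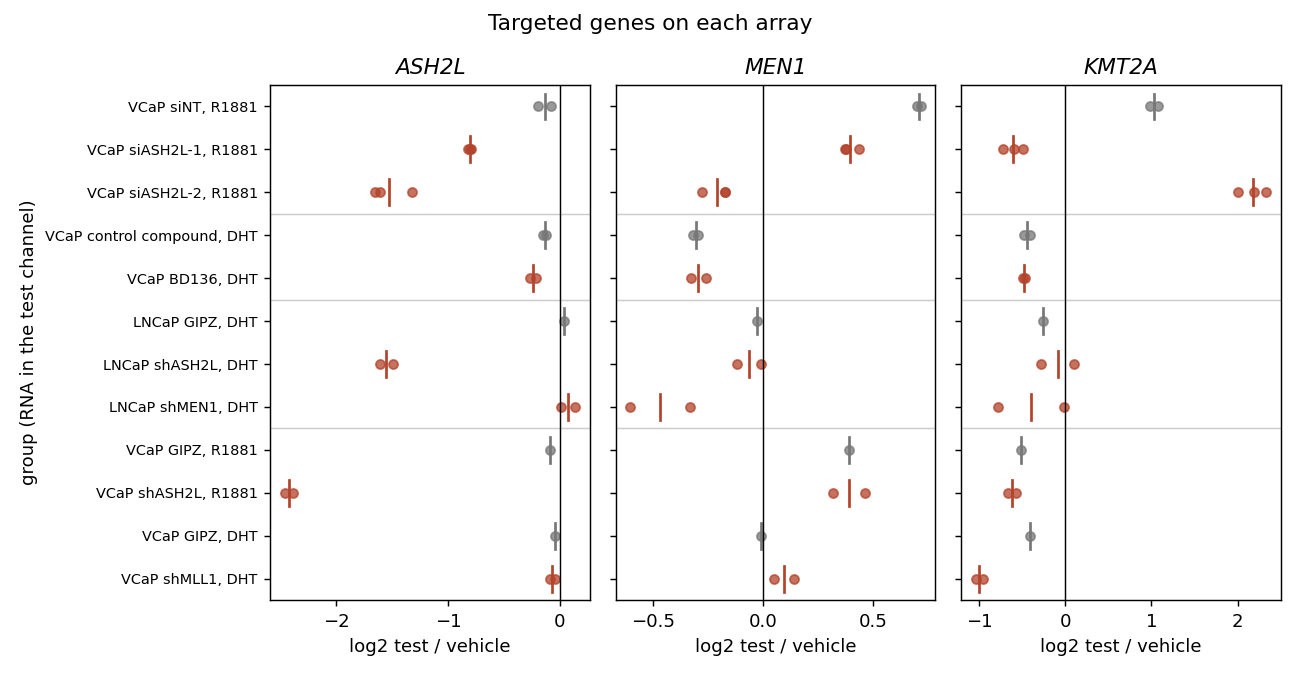
Log2 ratio of the androgen channel over the ethanol channel for ASH2L, MEN1 and KMT2A on each physical array, by group (points are arrays, vertical ticks group means, grey control groups, red knockdown or drug groups, and horizontal lines part the experiments). ASH2L lies at -1.32 or lower with siRNA 2 and all ASH2L hairpins and at -0.80 to -0.82 with siRNA 1, and KMT2A lies between 2.01 and 2.33 with ASH2L siRNA 2 but between -0.73 and -0.49 with siRNA 1.

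With non-targeting siRNA, R1881 raised the co-chaperone FKBP5 (4.49 ± 0.056), the retinoic acid-forming ALDH1A3 (4.62 ± 0.074), TMPRSS2 (1.71 ± 0.076) and ERG (1.18 ± 0.055) in VCaP cells. The neurotransmitter-synthesis enzyme DDC fell (-2.39 ± 0.063). BCHE, not well above background with R1881, was at least 5.82-fold lower. Androgen-induced genes rose as a list, with a median of 0.92 (adjusted p = 7.86e-05, or adjusted p = 0.33 with an estimated correlation) that was 0.54 under median centring. Of 50 measured, 37 rose and 12 fell (37 and 12 adjusted over the list alone). Androgen-repressed genes fell (adjusted p = 7.86e-05, or adjusted p = 0.0818 with an estimated correlation). Of 13 measured, 0 rose and 11 fell (0 and 11 adjusted over the list alone). The prostate antigen KLK3 rose by its brightest probe (0.89 ± 0.062), and its probes ranged from -0.72 to 0.89.

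Proliferation genes fell together with R1881 on these arrays, with a list median of -1.60 (adjusted p = 1.65e-08, or adjusted p = 0.0435 with an estimated correlation). Of 31 measured, 1 rose and 29 fell (1 and 29 adjusted over the list alone), with the mitotic protein CENPF at -2.82, the replication helicase subunit MCM3 at -2.48 and the topoisomerase TOP2A at -2.55. Unfolded protein response genes rose (adjusted p = 2.27e-06, or adjusted p = 0.187 with an estimated correlation). Of 23 measured, 19 rose and 1 fell (20 and 1 adjusted over the list alone), led by the chaperone DNAJB9 (4.63) and HERPUD1 (2.88). Interferon-stimulated genes fell (adjusted p = 0.0323, or adjusted p = 0.232 with an estimated correlation). Of 21 measured, 4 rose and 13 fell (4 and 13 adjusted over the list alone), with IFIT1 at -2.81 and MX1 at -2.29. MYC and ribosome biogenesis genes fell (adjusted p = 0.0484, or adjusted p = 0.232 with an estimated correlation). Of 16 measured, 3 rose and 10 fell (3 and 10 adjusted over the list alone), with RRS1 at -2.77 and MYC at -1.87 (probes -1.87 to 0.054). Sterol and lipid synthesis genes had a median of -0.086, with SREBF1 (-1.40) and SQLE (-1.09) falling.

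Within the MLL complex list WDR5 rose (1.80), as did MEN1 (0.71) and KMT2A (1.03, probes -0.16 to 1.03), and PSIP1 fell (-1.12). ASH2L did not pass (-0.14 ± 0.080). HOXA13, of the MLL and menin targets, fell (-4.11). The other 7 lists, luminal and sterol and lipid genes included, did not pass (adjusted p = 0.135 to 0.931). The largest rises were in the stress-inducible GADD45B (5.91), the Notch target HES1 (5.69), the sulfatase SULF2 (5.51) and the heat shock proteins HSPA4L (5.45) and HSPH1 (4.97). The largest falls were in SPRYD4 (-4.21), TMEM177 (-4.18), the Wnt ligand WNT2 (-3.85) and the prostate-specific membrane antigen FOLH1 (-3.80). In all, 7847 genes rose and 8924 fell of 22411 tested.

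These non-targeting arrays differed from the other androgen arrays in several measured ways. Their log2 ratios had a standard deviation of 0.848 to 0.852 over genes, against 0.471 to 0.481 with siRNA 1. Across genes they correlated at 0.359 to 0.362 with the control compound arrays, whereas the siRNA 1 arrays correlated at 0.736 to 0.746 with the same arrays. The median difference in log2 ratio between the probe nearest the 3' end and that nearest the 5' end of a gene was -0.379 and -0.393 on them, against -0.223 to -0.0578 on the 13 VCaP arrays without siRNA 2. A list of 24 measured heat shock and immediate early genes, written after the largest changes had been seen, had medians of 2.78 and 2.83 on them. The same list stood at 0.55 to 0.62 with siRNA 1 and 1.54 to 2.01 with siRNA 2. The response called 16761 genes with scan batch as a block, 16878 with slide as a random block and 18171 within the batch that held the control arrays.

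Against the non-targeting arrays, ASH2L siRNA lowered FKBP5 (-2.37 ± 0.065), ALDH1A3 (-3.14 ± 0.086), DNAJB9 (-3.71 ± 0.072) and WDR5 (-1.74 ± 0.071). It raised the androgen-induced transporter SLC45A3 (3.24 ± 0.066), the phosphatase PLPP1 (2.68 ± 0.081) and TMPRSS2 (0.93 ± 0.088). MEN1 fell (-0.62 ± 0.063). With siRNA 1 and siRNA 2 in turn, FKBP5 stood at -0.36 and -4.38, SLC45A3 at 5.23 and 1.25, TMPRSS2 at 1.31 and 0.56, and MEN1 at -0.31 and -0.92. KMT2A went opposite ways by its brightest probe, at -1.63 with siRNA 1 and 1.15 with siRNA 2, and its mean over both was -0.24 ± 0.10 (probes -0.28 to 0.19). ERG (-0.073 ± 0.063, probes -0.073 to 1.00) and KLK3 (-0.0059 ± 0.071, probes -0.0059 to 2.02) did not pass over both siRNAs. With siRNA 1 and siRNA 2 they stood at 0.46 and -0.61 for ERG and at -0.50 and 0.49 for KLK3. Androgen-induced genes went both ways, with a median of -0.049 (adjusted p = 0.544). Of 50 measured, 17 rose and 22 fell (18 and 22 adjusted over the list alone). Androgen-repressed genes rose (adjusted p = 0.0142, or adjusted p = 0.235 with an estimated correlation). Of 13 measured, 10 rose and 1 fell (11 and 1 adjusted over the list alone). They did not pass with siRNA 1 alone (median 0.30, adjusted p = 0.408), against a median of 0.94 with siRNA 2 (adjusted p = 0.00391, or adjusted p = 0.198 with an estimated correlation).

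Sterol and lipid synthesis genes rose almost throughout with ASH2L siRNA (adjusted p = 7.52e-06, or adjusted p = 0.278 with an estimated correlation). Of 24 measured, 23 rose and 0 fell (23 and 0 adjusted over the list alone), led by the epoxidase SQLE (2.42), FDFT1 (1.69) and IDI1 (1.88). Over ethanol, this list had a median of -0.086 on the non-targeting arrays, against 1.48 to 1.55 in the other VCaP control groups and 1.00 with siRNA 1. In the same contrast the heat shock and immediate early list, written after these arrays had been seen, had a median of -1.41. Proliferation genes were higher than with non-targeting siRNA (adjusted p = 0.00341, or adjusted p = 0.235 with an estimated correlation). Of 31 measured, 21 rose and 4 fell (23 and 4 adjusted over the list alone), with RRM2 at 2.39 and CCNB1 at 1.74 but the origin licensing factor CDC6 at -1.96. Interferon-stimulated genes rose (adjusted p = 0.00964, or adjusted p = 0.235 with an estimated correlation). Of 21 measured, 16 rose and 2 fell (16 and 2 adjusted over the list alone), with IFIT1 at 2.48 and ISG15 at 2.23. Unfolded protein response genes fell (adjusted p = 0.0204, or adjusted p = 0.354 with an estimated correlation). Of 23 measured, 6 rose and 15 fell (6 and 15 adjusted over the list alone), with XBP1 down (-2.44, at -0.89 with siRNA 1 and -3.98 with siRNA 2) and ATF4 up (1.81). The same list did not pass with siRNA 1 alone (median -0.36, adjusted p = 0.387), against -0.58 with siRNA 2 (adjusted p = 0.00675, or adjusted p = 0.347 with an estimated correlation). MLL and menin targets rose (adjusted p = 0.0142, or adjusted p = 0.354 with an estimated correlation). Of 14 measured, 8 rose and 0 fell (8 and 0 adjusted over the list alone), with HOXA13 at 3.15 and HOXA10 at 2.24. These targets did not pass with siRNA 1 alone (median 0.25, adjusted p = 0.351), where 7 rose and 4 fell of 14 (7 and 4 adjusted over the list alone). With siRNA 2 they had a median of 0.99 (adjusted p = 0.00225, or adjusted p = 0.347 with an estimated correlation), and 12 rose and 0 fell of 14 (12 and 0 adjusted over the list alone). Under median centring the sterol, proliferation, androgen-repressed and MLL and menin target medians of 0.75, 0.66, 0.65 and 0.49 became 0.38, 0.19, 0.38 and 0.30. With siRNA 2 alone the sterol and proliferation medians became -0.28 and -0.088. The other 7 lists, androgen-induced genes included, did not pass (adjusted p = 0.0774 to 0.885).

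The largest rises with ASH2L siRNA were in PGRMC2 (4.20), FASTKD5 (3.84) and the metal-binding metallothioneins MT2A (3.74), MT1G (3.57) and MT1E (3.49). MT1G stood at 4.78 with siRNA 1 and 2.36 with siRNA 2, and MT1E at 4.81 and 2.16. Metallothionein sequences are closely related, so their probes cannot be taken as specific. HSPA4L, not well above background with ASH2L siRNA, was at least 32-fold lower, and SULF2 (-5.30), TCAF2 (-4.21) and IL1R1 (-4.01) fell. In this contrast 8216 genes rose and 6997 fell of 22411. The count was 13926 with scan batch as a block, 15393 with slide as a random block and 16151 within the control arrays' batch. Androgen-induced medians were 0.020, -0.079 and 0.020 in turn. Against the ethanol channel of their own arrays, where knockdown and androgen cannot be told apart, 14819 genes were called with siRNA 1 and 16298 with siRNA 2.

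The 2 ASH2L siRNAs differed from each other in 14534 genes, 6906 higher and 7628 lower with siRNA 1. FKBP5 was higher with siRNA 1 (4.02 ± 0.065), at 4.11 to 4.16 over ethanol on its 3 arrays against 0.02 to 0.17 with siRNA 2. Also higher were SLC45A3 (3.98 ± 0.066), the androgen-induced SORD (2.99) and KLK2 (2.91), XBP1 (3.08), ERG (1.07), TMPRSS2 (0.76), MEN1 (0.60) and ASH2L itself (0.72). KMT2A (-2.78 ± 0.10, probes -2.78 to -0.16), DDC (-3.89), HOXA9 (-2.41) and the cell cycle inhibitor CDKN1C (-6.13) were lower. KLK3 was lower by its brightest probe (-0.99), with probes from -0.99 to 3.32. Not well above background with siRNA 2, ORM2 was at least 25.6-fold and STEAP4 at least 10.1-fold higher with siRNA 1. On the siRNA 2 arrays 46.8% to 51.8% of spots were well above background in the androgen channel, against 55.8% to 60.4% with siRNA 1. Across genes they correlated at 0.113 to 0.127 with the control compound arrays, against 0.736 to 0.746 with siRNA 1. The median 3' minus 5' probe difference was -0.258 to -0.182 on them, against -0.120 to -0.111 with siRNA 1. The heat shock and immediate early list had a median of -1.42 between the siRNAs.

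By list, androgen-induced genes were higher with siRNA 1 (adjusted p = 1.23e-06, or adjusted p = 0.275 with an estimated correlation). Of 50 measured, 35 rose and 9 fell (35 and 9 adjusted over the list alone). Luminal markers were higher (adjusted p = 0.00667, or adjusted p = 0.238 with an estimated correlation). Of 12 measured, 9 rose and 3 fell (9 and 3 adjusted over the list alone). Unfolded protein response genes were higher (adjusted p = 0.00781, or adjusted p = 0.28 with an estimated correlation), and of 23 measured, 15 rose and 5 fell (15 and 5 adjusted over the list alone). Sterol and lipid genes were higher (adjusted p = 0.00781, or adjusted p = 0.352 with an estimated correlation), and of 24 measured, 15 rose and 4 fell (15 and 5 adjusted over the list alone). Androgen-repressed genes were lower (adjusted p = 0.00781, or adjusted p = 0.238 with an estimated correlation). Of 13 measured, 1 rose and 9 fell (1 and 9 adjusted over the list alone). MLL and menin targets were lower (adjusted p = 0.00781, or adjusted p = 0.28 with an estimated correlation), and of 14 measured, 2 rose and 11 fell (2 and 11 adjusted over the list alone). Proliferation genes were lower (adjusted p = 0.0111, or adjusted p = 0.238 with an estimated correlation). Of 31 measured, 5 rose and 20 fell (5 and 21 adjusted over the list alone). Interferon-stimulated genes were lower (adjusted p = 0.0193, or adjusted p = 0.238 with an estimated correlation), and of 21 measured, 2 rose and 12 fell (2 and 12 adjusted over the list alone). Targets of p53 were lower (adjusted p = 0.0156, or adjusted p = 0.238 with an estimated correlation), and of 12 measured, 1 rose and 9 fell (1 and 9 adjusted over the list alone). The medians of these last 3 lists turned positive when ratios were centred on the median in place of loess, at 0.37, 0.091 and 0.11. Those of androgen-repressed genes and MLL and menin targets went from -0.91 and -0.68 to -0.49 and -0.30. The other 4 lists did not pass between the siRNAs (adjusted p = 0.188 to 0.556). Against non-targeting siRNA, androgen-induced genes had a median of 0.35 with siRNA 1 (adjusted p = 0.0289, or adjusted p = 0.562 with an estimated correlation) and -0.19 with siRNA 2 (adjusted p = 0.0453, or adjusted p = 0.515 with an estimated correlation). E1A control spots, outside the gene measurements, read 1.53 to 1.59 with siRNA 2 against -0.17 to -0.15 with siRNA 1. The count was 14437 with scan batch as a block, 14447 with slide as a random block, and 13804 and 11157 within the separate batches.

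In the drug experiment, DHT with the control compound raised FKBP5 (3.84 ± 0.051), TMPRSS2 (3.31 ± 0.067), ERG (2.11 ± 0.046) and the transcription elongation factor EAF2 (3.40 ± 0.052) over 2 arrays. It lowered DDC (-3.26 ± 0.049), HSD17B6 (-2.25 ± 0.048) and BCHE (-2.65 ± 0.062). Androgen-induced genes rose (adjusted p = 6.03e-17, or adjusted p = 0.105 with an estimated correlation). Of 50 measured, 45 rose and 1 fell (45 and 1 adjusted over the list alone). Androgen-repressed genes fell (adjusted p = 0.00373, or adjusted p = 0.21 with an estimated correlation). Of 12 measured, 3 rose and 9 fell (3 and 9 adjusted over the list alone). Sterol and lipid synthesis genes rose, with a median of 1.55 (adjusted p = 1.6e-11, or adjusted p = 0.105 with an estimated correlation). Of 24 measured, 23 rose and 0 fell (24 and 0 adjusted over the list alone), including INSIG1 (2.73) and IDI1 (2.60). ASH2L (-0.14 ± 0.047), MEN1 (-0.31 ± 0.048) and KMT2A (-0.44 ± 0.048) fell, and KLK3 did not pass (0.11 ± 0.064, probes 0.11 to 2.04). Those falls of ASH2L, MEN1 and KMT2A turned positive under median centring, at 0.39, 0.12 and 0.15.

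With DHT, unfolded protein response genes rose (adjusted p = 1.13e-06, or adjusted p = 0.108 with an estimated correlation). Of 23 measured, 20 rose and 2 fell (20 and 2 adjusted over the list alone), with SDF2L1 at 2.15. Luminal markers rose (adjusted p = 0.0326, or adjusted p = 0.278 with an estimated correlation). Of 12 measured, 8 rose and 2 fell (8 and 2 adjusted over the list alone), with KRT18 at 1.44. Proliferation genes fell (adjusted p = 0.000355, or adjusted p = 0.127 with an estimated correlation). Of 31 measured, 4 rose and 21 fell (4 and 21 adjusted over the list alone), with MCM2 at -1.11. MYC and ribosome biogenesis genes fell (adjusted p = 2.02e-06, or adjusted p = 0.108 with an estimated correlation). Of 16 measured, 0 rose and 15 fell (0 and 15 adjusted over the list alone), with RRS1 at -1.19 and the brightest MYC probe at -3.38 (probes -3.38 to 0.13). Under median centring the proliferation and MYC medians of -0.49 and -0.71 became -0.010 and -0.16. The other 6 lists did not pass with DHT (adjusted p = 0.123 to 0.989). The largest rises were in the acyl-CoA binding protein DBI (4.36), the racemase AMACR (4.12) and ACSL3 (4.03), with STEAP4 at least 19.3-fold higher. The largest falls were in WNT2 (-4.51), TRIB1 (-3.97), CCN3 (-3.95) and FOLH1 (-3.46). Altogether 6730 genes rose and 6958 fell of 22188.

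BD136 lowered the androgen-induced list in DHT-treated VCaP cells, with a median of -0.23 (adjusted p = 1.79e-06, or adjusted p = 0.109 with an estimated correlation). Of 50 measured, 3 rose and 20 fell (3 and 23 adjusted over the list alone). TMPRSS2 fell (-0.84 ± 0.095, adjusted p = 0.00696), as did ERG (-0.58 ± 0.065, adjusted p = 0.00687) and FKBP5 (-0.52 ± 0.072, adjusted p = 0.0111). ORM1 (-1.36 ± 0.085), the prostaglandin dehydrogenase HPGD (-0.90 ± 0.065) and the epithelial transcription factor SPDEF (-0.78 ± 0.071) fell too, and all these genes were lower on 2 of 2 arrays. KLK3 did not pass (-0.20 ± 0.090). Androgen-repressed genes went both ways, with a rise of HSD17B6 (0.80 ± 0.068) and a fall of the steroid-converting AKR1C3 (-1.59 ± 0.079).

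Sterol and lipid synthesis genes, already raised by DHT, were higher still with BD136 (adjusted p = 1.64e-08, or adjusted p = 0.109 with an estimated correlation). Of 24 measured, 13 rose and 0 fell (16 and 1 adjusted over the list alone), led by HMGCS1 (1.58 ± 0.13), FDPS (1.23 ± 0.10) and the desaturase SCD (1.11 ± 0.074). Genes of MYC and ribosome biogenesis rose (adjusted p = 4.31e-08, or adjusted p = 0.109 with an estimated correlation). Of 16 measured, 9 rose and 0 fell (13 and 0 adjusted over the list alone), with RRS1 at 0.84 and MYC at 0.80 (probes -0.024 to 0.80). Targets of p53 fell (adjusted p = 0.00463, or adjusted p = 0.256 with an estimated correlation). Of 12 measured, 0 rose and 5 fell (0 and 6 adjusted over the list alone), including FAS (-0.54) and BTG2 (-0.53). Under median centring the sterol and MYC medians of 0.41 and 0.39 became 0.22 and 0.20. The proliferation list did not pass (adjusted p = 0.0922). Of 31 measured, 5 rose and 12 fell (11 and 15 adjusted over the list alone), with TOP2A at -1.08, UBE2C at -0.95 and the brightest PLK1 probe at -1.34 (probes -1.34 to -0.0055). In the unfolded protein response list PSAT1 (1.05) and ATF4 (0.59) rose and ATF3 (-1.30) and DDIT3 (-0.79) fell. Among MLL and menin targets PBX3 (-0.80), CDKN1B (-0.55) and HOXA9 (-0.43) fell. With BD136 the other 9 lists, these last 3 included, did not pass (adjusted p = 0.0922 to 0.729).

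The largest rises with BD136 were in CEP15 (1.83), TMEFF2 (1.71) and the growth factor TGFB2 (1.63). The largest falls were in LAMP3 (-2.05), NDRG4 (-1.65), the cyclooxygenase PTGS1 (-1.55) and AKR1C1 (-1.50). A total of 1512 genes rose and 1404 fell of 22188, 93 of them by at least 2-fold. The count was 47 without BD136 array 1 and 126 without BD136 array 2, 1089 with the Feature Extraction ratio, and 6001 with median centring, 15.0% of them higher against 51.9%. The control compound and BD136 arrays lay on separate slides, so slide and compound cannot be told apart.

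**Figure D2:**
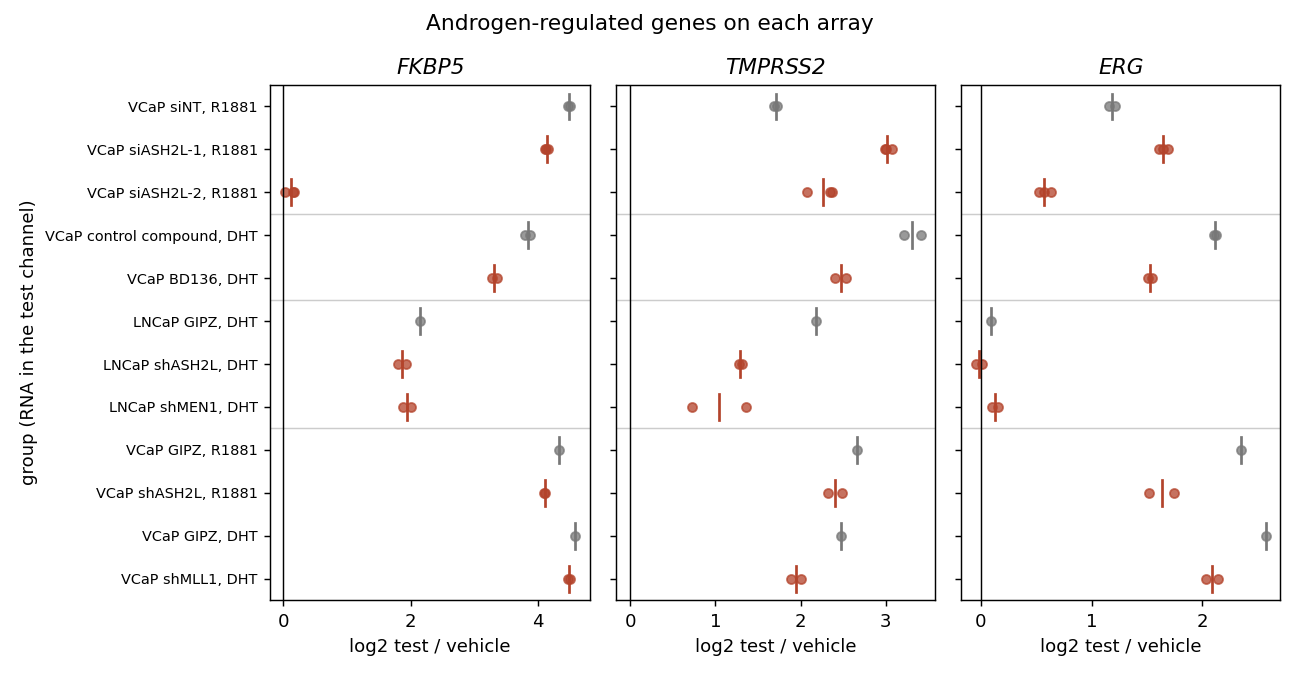
Log2 ratio of the androgen channel over the ethanol channel for FKBP5, TMPRSS2 and ERG on each physical array, by group (points are arrays, vertical ticks group means, grey control groups, red knockdown or drug groups, and horizontal lines part the experiments). FKBP5 lies between 0.02 and 0.17 with ASH2L siRNA 2 against 4.11 to 4.16 with siRNA 1, and BD136 arrays lie at 3.27 and 3.35 against 3.88 and 3.79 with the control compound.

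In LNCaP cells with the GIPZ vector, DHT raised FKBP5 (2.15 ± 0.087), TMPRSS2 (2.18 ± 0.22), EAF2 (2.70 ± 0.094) and the GTPase RHOU (2.16 ± 0.084). Androgen-induced genes rose as a group (adjusted p = 1.12e-31, or adjusted p = 0.146 with an estimated correlation). Of 50 measured, 39 rose and 0 fell (47 and 1 adjusted over the list alone). Androgen-repressed genes fell (adjusted p = 0.000185, or adjusted p = 0.42 with an estimated correlation). Of 13 measured, 0 rose and 3 fell (0 and 7 adjusted over the list alone), including the glucuronosyltransferases UGT2B15 (-1.04) and UGT2B17 (-0.74). The list's median of -0.50 became -0.048 under median centring. Unfolded protein response genes rose (adjusted p = 9.59e-15, or adjusted p = 0.146 with an estimated correlation). Of 23 measured, 14 rose and 0 fell (19 and 0 adjusted over the list alone), with DNAJB9 at 2.97 and ATF3 at 2.34. ASH2L (0.038 ± 0.089), MEN1 (-0.028 ± 0.12), KMT2A (-0.26 ± 0.29, probes -0.26 to 0.18) and KLK3 (-0.10 ± 0.073, probes -0.10 to 1.93) did not pass. ERG was not well enough above background to be tested in this line.

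Proliferation genes were lower with DHT (adjusted p = 6.35e-09, or adjusted p = 0.562 with an estimated correlation), and of 31 measured, 0 rose and 2 fell (0 and 10 adjusted over the list alone), MCM2 among them (-0.61). Lower too were MYC and ribosome biogenesis genes (adjusted p = 0.000185, or adjusted p = 0.42 with an estimated correlation). Of 16 measured, 0 rose and 3 fell (0 and 6 adjusted over the list alone), with RRS1 at -1.05. Interferon-stimulated genes were lower as a list (adjusted p = 0.0391, or adjusted p = 0.468 with an estimated correlation), although of 22 measured, 0 rose and 0 fell (0 and 0 adjusted over the list alone). The medians of these 3 lists turned positive under median centring, at 0.17, 0.32 and 0.16. The other 7 lists did not pass in LNCaP (adjusted p = 0.323 to 0.995). The transcription factor SNAI2 (2.76, probes 0.10 to 2.76), KRT19 (1.53), the differentiation inhibitor ID1 (2.58) and HEY1 (2.42) rose, and NAPEPLD (-2.27) and DGAT2 (-1.40) fell. TTC17 (2.70) was called from the second scan of the control array alone, where it read 5.43 against -0.04 on the first scan. In all 1030 genes rose and 459 fell of 25108. The count was 12782 with median centring and 2582 with no background correction. It was 6741 without either MEN1 hairpin array, and limma called 0 without either ASH2L hairpin array, with 3788 at an unadjusted p under 0.05, since the hairpin arrays supply the spread for the lone control array.

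Few genes passed with ASH2L hairpins in LNCaP, at low power. PIP, a secreted protein of prostate and breast, rose (2.46 ± 0.13, adjusted p = 0.0396), and in all 3 genes rose and 4 fell of 25108, with 895 at an unadjusted p under 0.05 in limma. Androgen-induced genes stood lower as a list, with a median of -0.22 (adjusted p = 1.11e-06, or adjusted p = 0.343 with an estimated correlation), and of -0.072, which did not pass, with the second scans alone. Of 50 measured, 0 rose and 0 fell (1 and 1 adjusted over the list alone). TMPRSS2 (-0.89 ± 0.26), FKBP5 (-0.28 ± 0.11), KLK3 (-0.25 ± 0.089, probes -0.25 to 1.00), MEN1 (-0.034 ± 0.14) and KMT2A (0.17 ± 0.35, probes -0.20 to 0.17) did not pass. Interferon-stimulated genes stood lower (adjusted p = 0.000306, or adjusted p = 0.343 with an estimated correlation), and of 22 measured, 0 rose and 0 fell (0 and 2 adjusted over the list alone). Sterol and lipid genes stood lower (adjusted p = 0.0281, or adjusted p = 0.343 with an estimated correlation), and of 24 measured, 0 rose and 0 fell (0 and 0 adjusted over the list alone). So did MLL complex genes, of which ASH2L is a member (adjusted p = 0.0281, or adjusted p = 0.343 with an estimated correlation), and of 20 measured, 0 rose and 0 fell (0 and 1 adjusted over the list alone). Neuroendocrine markers stood lower (median -0.085, or -0.051 under median centring, adjusted p = 0.0281, or adjusted p = 0.351 with an estimated correlation), and of 7 measured, 0 rose and 0 fell (0 and 0 adjusted over the list alone). MYC and ribosome biogenesis genes stood higher, with a median of 0.061 (adjusted p = 0.0244, or adjusted p = 0.343 with an estimated correlation) that became -0.32 under median centring, and of 16 measured, 0 rose and 0 fell (0 and 0 adjusted over the list alone).

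With ASH2L hairpins in LNCaP the other 7 lists did not pass (adjusted p = 0.053 to 0.968). TTC17 (-2.78, probes -2.78 to 0.18), SUMO1P1 (-1.80) and CYP2F1 (1.60) were called from the second scan of the control array. With its first scan alone limma called 0 genes, with 890 at an unadjusted p under 0.05. The count was 0 without hairpin array 1 (438 at an unadjusted p under 0.05), 0 without array 2 (270) and 131 without either MEN1 hairpin array. The control array lay on another slide than all hairpin arrays, so slide and knockdown cannot be told apart in this line.

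MEN1 hairpins in LNCaP raised PIP (3.85 ± 0.13), and UGT2B28 (2.49 ± 0.14) and UGT2B7 (2.49 ± 0.18) of the androgen-repressed list. They lowered CAMK2N1 (-2.36 ± 0.18) of the same list and the adhesion receptor ADGRG6 (-2.67 ± 0.13). TMPRSS2 (-1.14 ± 0.26), FKBP5 (-0.20 ± 0.11, probes -0.20 to 0.27), KLK3 (-0.043 ± 0.089, probes -0.043 to 1.22), ASH2L (0.036 ± 0.11) and KMT2A (-0.14 ± 0.35) did not pass. In total 20 genes rose and 19 fell of 25108, with 3784 at an unadjusted p under 0.05 in limma.

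None of the 13 lists passed with MEN1 hairpins (adjusted p = 0.0645 to 0.895). Androgen-induced genes had a median of -0.20 (adjusted p = 0.158). Among androgen-repressed genes 2 rose and 1 fell of 13 (4 and 4 adjusted over the list alone). TTC17, CYP2F1 and SUMO1P1 were again called from the second control scan, and with the first scan alone 35 genes were called. The count was 11030 with median centring, 145 with the authors' processed values, 3670 without MEN1 hairpin array 1 and 3039 without array 2. With limma it was 0 with the Feature Extraction ratio (3455 at an unadjusted p under 0.05) and 0 without either ASH2L hairpin array (2012).

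On the VCaP GIPZ arrays, R1881 raised FKBP5 (4.33 ± 0.10), TMPRSS2 (2.66 ± 0.11), ERG (2.35 ± 0.11) and the fatty acid ligase ACSL3 (4.18 ± 0.11), and lowered UGT2B15 (-3.16 ± 0.11). With DHT these genes stood at 4.59 ± 0.10, 2.47 ± 0.11, 2.57 ± 0.11, 4.25 ± 0.11 and -3.30 ± 0.11. STEAP4, not well above background in ethanol, was at least 23.9-fold higher with R1881 and at least 22.4-fold higher with DHT. Androgen-induced genes rose with R1881 (adjusted p = 7.19e-23, or adjusted p = 0.0846 with an estimated correlation), and of 50 measured, 41 rose and 1 fell (42 and 1 adjusted over the list alone). They rose with DHT (adjusted p = 1.7e-24, or adjusted p = 0.0789 with an estimated correlation), and of 50 measured, 45 rose and 0 fell (45 and 0 adjusted over the list alone). Androgen-repressed genes fell with R1881 (adjusted p = 9.95e-08, or adjusted p = 0.178 with an estimated correlation), and of 13 measured, 1 rose and 12 fell (1 and 12 adjusted over the list alone). They fell with DHT (adjusted p = 4.63e-06, or adjusted p = 0.157 with an estimated correlation), and of 13 measured, 2 rose and 11 fell (2 and 11 adjusted over the list alone). KLK3 did not pass with R1881 (-0.018 ± 0.12, probes -0.018 to 2.23) or DHT (-0.0086 ± 0.12, probes -0.0086 to 2.64). MEN1 rose with R1881 (0.39 ± 0.11) and did not pass with DHT (-0.0079 ± 0.11), a difference of 0.40 that did not pass (adjusted p = 0.0706). KMT2A fell with both (-0.52 ± 0.10 and -0.41 ± 0.10), and ASH2L passed with neither (-0.089 ± 0.10 and -0.039 ± 0.10).

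Sterol and lipid genes rose with R1881 (adjusted p = 5.47e-17, or adjusted p = 0.244 with an estimated correlation), and of 23 measured, 22 rose and 0 fell (22 and 0 adjusted over the list alone). They rose with DHT (adjusted p = 9.79e-17, or adjusted p = 0.248 with an estimated correlation), and of 24 measured, 24 rose and 0 fell (24 and 0 adjusted over the list alone), with IDI1 at 3.62 and 2.85. Unfolded protein response genes rose with R1881 (adjusted p = 0.000444, or adjusted p = 0.237 with an estimated correlation), and of 23 measured, 12 rose and 3 fell (12 and 5 adjusted over the list alone). With DHT they rose (adjusted p = 3.97e-08, or adjusted p = 0.156 with an estimated correlation), and of 23 measured, 16 rose and 0 fell (16 and 0 adjusted over the list alone), with SDF2L1 at 3.50 and 2.22. Luminal markers rose with R1881 (adjusted p = 0.000309, or adjusted p = 0.397 with an estimated correlation), and of 11 measured, 7 rose and 1 fell (8 and 1 adjusted over the list alone). With DHT they rose (adjusted p = 0.0152, or adjusted p = 0.542 with an estimated correlation), and of 12 measured, 6 rose and 1 fell (6 and 1 adjusted over the list alone), though that median was -0.23 under median centring. The same centring moved the luminal median with R1881 from 0.66 to 0.037, and the unfolded protein response medians from 0.38 with R1881 and 0.96 with DHT to 0.093 and 0.24. MYC and ribosome biogenesis genes fell with R1881 (adjusted p = 0.000309, or adjusted p = 0.258 with an estimated correlation), and of 16 measured, 0 rose and 14 fell (0 and 14 adjusted over the list alone). With DHT they fell (adjusted p = 0.00419, or adjusted p = 0.343 with an estimated correlation), and of 16 measured, 0 rose and 11 fell (0 and 11 adjusted over the list alone). The brightest MYC probe read -2.81 and -4.22 (probes -2.81 to 0.040 and -4.22 to 0.045). MLL and menin targets fell with DHT (adjusted p = 0.0361, or adjusted p = 0.343 with an estimated correlation), and of 15 measured, 0 rose and 7 fell (0 and 7 adjusted over the list alone), with HOXA13 at -0.74. They did not pass with R1881 (adjusted p = 0.344), and the difference between the androgens did not pass either (adjusted p = 0.165).

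The other 6 lists passed with neither androgen (adjusted p = 0.204 to 0.828 with R1881, MLL and menin targets included, and 0.284 to 0.913 with DHT). EAF2 (4.06 and 4.79), ORM2 (3.91 and 4.39) and AMACR (3.85 and 3.78) rose with R1881 and DHT. WNT2 (-3.65 and -3.99), FOLH1 (-3.03 and -4.93) and TRIB1 (-3.36 and -3.63) fell with both. With R1881 4568 genes rose and 5790 fell of 21909, and with DHT 4918 rose and 6283 fell of 21985. Each response rests on 1 array, assumed to vary like the hairpin arrays.

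ASH2L hairpins in VCaP, with R1881, raised the androgen-induced transcription factor MAF (1.92 ± 0.15) and lowered STEAP4 (-1.05 ± 0.16), UAP1 (-0.87 ± 0.16) and SLC45A3 (-0.62 ± 0.13) of the same list. ERG fell by its brightest probe (-0.72 ± 0.14, probes -0.72 to 0.25). FKBP5 (-0.23 ± 0.12), TMPRSS2 (-0.25 ± 0.13), KLK3 (0.013 ± 0.14, probes -0.43 to 0.089), MEN1 (0.00040 ± 0.13) and KMT2A (-0.10 ± 0.13, probes -0.10 to 0.16) did not pass. Androgen-induced genes were lower as a list, with a median of -0.17 (adjusted p = 0.0419, or adjusted p = 0.644 with an estimated correlation) that became 0.11 under median centring and -0.091 without ASH2L hairpin array 1. Of 50 measured, 3 rose and 5 fell (3 and 12 adjusted over the list alone). Proliferation genes rose (adjusted p = 0.00323, or adjusted p = 0.694 with an estimated correlation). Of 31 measured, 15 rose and 1 fell (15 and 3 adjusted over the list alone), with the replication factors PCNA at 1.09, MCM5 at 1.20 and MCM2 at 0.98. So did MYC and ribosome biogenesis genes (adjusted p = 3.48e-06, or adjusted p = 0.644 with an estimated correlation). Of 16 measured, 5 rose and 0 fell (7 and 0 adjusted over the list alone), with FBL at 0.76 and MYC at 1.06 (probes -0.066 to 1.06).

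Luminal markers were lower with ASH2L hairpins in VCaP (adjusted p = 0.00323, or adjusted p = 0.694 with an estimated correlation), with a list median of 0.10 under median centring. Of 11 measured, 0 rose and 2 fell (0 and 4 adjusted over the list alone), with MSMB at -0.92 and ACP3 at -0.56. Interferon-stimulated genes were lower (adjusted p = 0.0371, or adjusted p = 0.694 with an estimated correlation). Of 22 measured, 0 rose and 2 fell (0 and 3 adjusted over the list alone), with IFIT2 at -0.95 and a list median of -0.20, or -0.092 under median centring. The neuroendocrine transcription factor INSM1 fell (-1.73, probes -1.73 to -0.038). The other 8 lists did not pass with ASH2L hairpins (adjusted p = 0.135 to 0.89). Other large falls were HHLA2 (-2.86), ZMYND10 (-2.09) and the aldehyde dehydrogenase ALDH2 (-2.03). RORB was at least 3.77-fold higher, SLC1A1 rose (1.48), and TMEFF2 rose by its brightest probe (2.14, probes -0.59 to 2.14). In all 631 genes rose and 1172 fell of 21909, and 15 were called with the Feature Extraction ratio and 832 with the authors' processed values.

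MLL1 hairpins in VCaP, with DHT, raised the nuclear lamin LMNB1 (1.52 ± 0.18), the co-chaperone DNAJC7 (1.31 ± 0.17), the secretoglobin SCGB1D2 (1.31 ± 0.17) and the zinc transporter SLC30A4 (1.28 ± 0.14). They lowered LGI1 (-1.55 ± 0.14), the cyclin CCNJ (-1.51 ± 0.14) and the sialyltransferase ST6GAL1 (-1.39 ± 0.14). TMPRSS2 (-0.52 ± 0.13), ERG (-0.48 ± 0.14), FKBP5 (-0.10 ± 0.12), KLK3 (0.095 ± 0.14, probes -0.26 to 0.095), ASH2L (-0.027 ± 0.13) and MEN1 (0.10 ± 0.13) did not pass. Androgen-induced genes stood lower as a list, with a median of -0.079 (adjusted p = 0.0142, or adjusted p = 0.583 with an estimated correlation). Of 50 measured, 0 rose and 0 fell (0 and 4 adjusted over the list alone). Proliferation genes stood higher, with a median of 0.29 (adjusted p = 0.000324, or adjusted p = 0.907 with an estimated correlation). Of 31 measured, 0 rose and 0 fell (9 and 0 adjusted over the list alone). MYC and ribosome biogenesis genes stood higher, with a median of 0.17 (adjusted p = 0.000324, or adjusted p = 0.583 with an estimated correlation), or 0.098 under median centring. Of 16 measured, 0 rose and 0 fell (1 and 0 adjusted over the list alone).

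With MLL1 hairpins the other 10 lists did not pass (adjusted p = 0.572 to 0.822). Across all genes 19 rose and 19 fell of 21985, with 2209 at an unadjusted p under 0.05 in limma. The count was 0 with the Feature Extraction ratio (1943 at an unadjusted p under 0.05), 0 with the authors' processed values (2080), and 269 without either ASH2L hairpin array, which share the estimate of spread. The control and MLL1 arrays lay on separate slides, so slide and knockdown cannot be told apart.

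**Figure D3:**
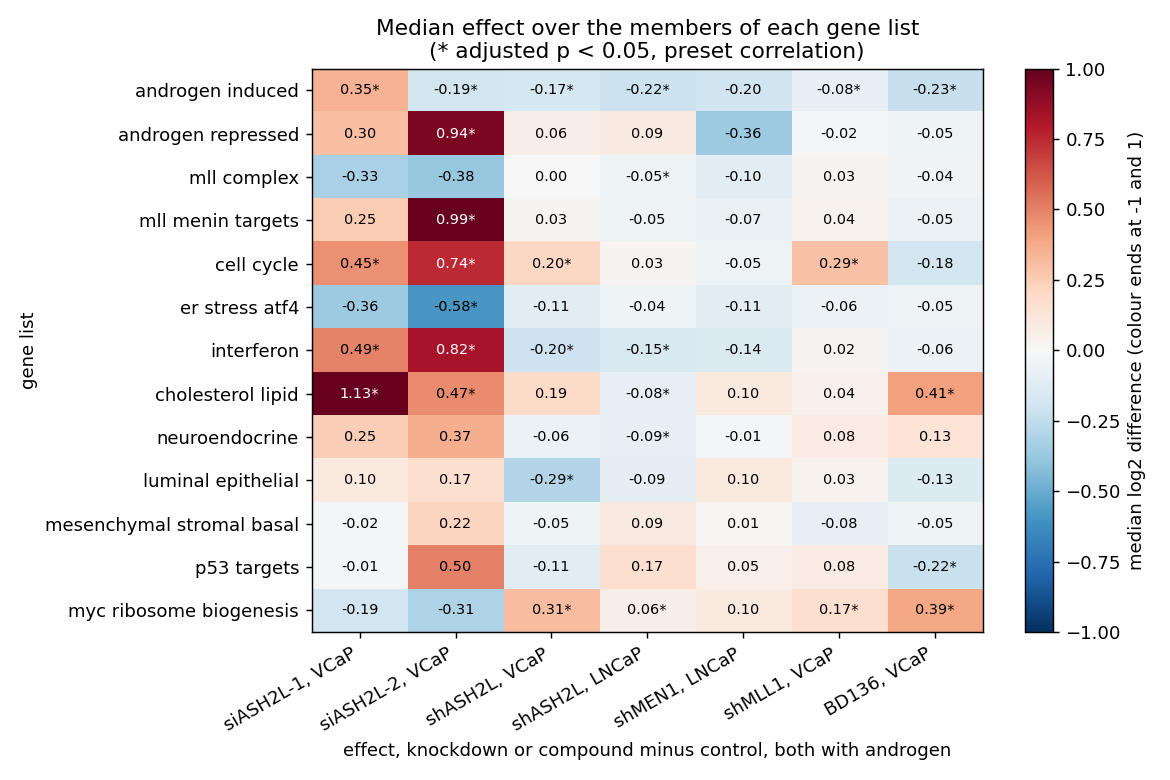
Median log2 difference of the measured members of each of 13 gene lists in each knockdown or drug effect (colour, log2, ending at -1 and 1; an asterisk marks an adjusted p under 0.05 with the preset correlation). Sterol and lipid genes stand at 1.13 with ASH2L siRNA 1, 0.47 with siRNA 2 and 0.41 with BD136. Androgen-induced genes stand at -0.23 with BD136, -0.17 with ASH2L hairpins and -0.079 with MLL1 hairpins in VCaP.

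Selecting and measuring genes on the same control arrays would by itself give a fall, so genes raised by androgen in 1 experiment were also followed in another. Genes raised at least 2-fold by R1881 on the non-targeting siRNA arrays were lower with BD136 (median -0.082, p = 7.48e-06, or p = 0.00856 with an estimated correlation). Of 2553 such genes 111 rose and 361 fell. Genes raised at least 2-fold both there and with the control compound were lower with the ASH2L hairpins in VCaP (median -0.16, p = 3.29e-07, or p = 0.0541 with an estimated correlation). Of these 357 genes 2 rose and 42 fell. They were also lower with the MLL1 hairpins (median -0.10, p = 3.72e-09, or p = 0.0414 with an estimated correlation), where 0 rose and 1 fell of 361. With genes raised by a log2 of at least 0.58 in place of 1, the MLL1 median was -0.077 and that call was lost with an estimated correlation (p = 0.102). Genes raised by DHT with the control compound were lower with ASH2L siRNA (median -0.21, p = 0.00582, or p = 0.350 with an estimated correlation), at 0.25 with siRNA 1 and -0.63 with siRNA 2. Of these 802 genes 262 rose and 397 fell. As alternatives chosen after the data had been seen and without the siRNA controls, the drug set stood at -0.17 with ASH2L hairpins (p = 2.57e-08, or p = 0.0950 with an estimated correlation). It stood at -0.090 with MLL1 hairpins (p = 4.68e-09, or p = 0.0870 with an estimated correlation). The set raised on both VCaP GIPZ arrays stood at -0.17 with BD136 (44 rose and 156 fell of 572, p = 3.86e-09, or p = 0.00436 with an estimated correlation).

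Across genes, which are not independent replicates, the effects of different reagents correlated weakly between experiments. BD136 and the MLL1 hairpins had a Pearson r of 0.20 over 21352 genes, BD136 and the LNCaP ASH2L hairpins 0.12, and the ASH2L hairpins in LNCaP and VCaP 0.12. Between ASH2L siRNA and ASH2L hairpins in VCaP r was 0.021, and between ASH2L siRNA and the MEN1 hairpins -0.21. Genes raised by both BD136 and the VCaP ASH2L hairpins numbered 124, against 43.7 for independent lists, and genes lowered by both 158, against 73.7. The LNCaP ASH2L and MEN1 effects, which share their control array, had r = 0.36 and a covariance of 0.0159. In 100 simulations unchanged groups against that array gave r = 0.667, which array numbers fix, and a covariance of 0.0221 (0.0207 to 0.0247). Spread between hairpins entered the latter, so a shared effect stays undecided.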

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

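The tests of probe position (made separate for the 2 siRNA groups after a joint test had not decided), LNCaP RNA, stress genes, ratio compression, slides, the control array and its scans were chosen after the result they bear on had been seen. The differences between cell lines and androgens were tested in 1 fit of all 23 arrays, which set the spread.

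The effect of ASH2L hairpins differed between LNCaP with DHT and VCaP with R1881 in 609 of 21339 genes, 404 higher and 205 lower in LNCaP. FABP5 was higher in LNCaP (2.37), and ASH2L itself differed by 0.74 (adjusted p = 0.0257), but by 0.023 under median centring. Proliferation (median -0.37), sterol and lipid (-0.29) and MYC and ribosome biogenesis genes (-0.24) were lower and luminal markers higher (0.21, but -0.59 under median centring), none of them with an estimated correlation (adjusted p = 0.0901 to 0.569). Under median centring the first 3 medians were -0.84, -0.85 and -1.001. The androgen response to DHT differed between LNCaP and VCaP GIPZ arrays in 8705 of 21415 genes, 5094 higher and 3611 lower in LNCaP. FOLH1 (4.86), TRIB1 (4.78) and IGFBP3 (4.65) were higher, and AMACR (-3.61) and FKBP5 (-2.44) lower. Sterol and lipid genes were lower by the list test (median -1.34, adjusted p = 2.21e-18, or adjusted p = 0.0152 with an estimated correlation), and androgen-repressed genes were higher (1.37, adjusted p = 2.38e-04, or adjusted p = 0.119 with an estimated correlation). Under median centring these medians were -0.43 and 2.35, and FKBP5 differed by -1.52. Androgen-induced (median -0.25, adjusted p = 0.00172, or adjusted p = 0.357 with an estimated correlation) and proliferation genes (-0.38, adjusted p = 0.00115, or adjusted p = 0.414 with an estimated correlation) were lower, but stood at 0.57 and 0.44 under median centring. Treatment time, dye orientation and slide differed between these lines too, at 12 h in LNCaP and 24 h in VCaP. R1881 and DHT differed on the VCaP GIPZ arrays, 1 each on separate slides, in 1670 of 21339 genes, 948 higher and 722 lower with R1881. BTN3A3 (2.05), FOLH1 (1.89) and MSMB (1.71) were higher with R1881, and SLC7A11 (-1.69), AKR1B10 (-1.58) and HMOX1 (-1.36) lower. Androgen-induced genes were lower with R1881 (median -0.17, or -0.084 under median centring) and luminal markers higher (median 0.21). E1A control spots read 1.53 to 1.59 on the siRNA 2 arrays against -0.86 to 0.25 in every other group.

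The first pattern is that the non-targeting and siRNA 2 arrays stand apart from the other VCaP androgen arrays. The difference between the probes nearest the 3' and 5' ends reached -0.393 on the non-targeting arrays, beyond the -0.223 to -0.0578 of the 13 other arrays by over 0.1, so degraded or differently primed RNA may contribute there, although lower 3' signal is opposite to what degradation gives with dT priming. With siRNA 2 it was -0.250, -0.258 and -0.182, and the median absolute difference was 0.440, 0.437 and 0.323 against at most 0.338 on the other arrays, so this cause stays open there. RNA of LNCaP cells was excluded for both groups, since the 50 brightest LNCaP genes not above background in VCaP ethanol channels had medians up to 0.0740, while a biological difference between the siRNAs stays open, and so does a stress response, because the heat shock and immediate early list, at least 0.926 higher on both groups' arrays than on the siRNA 1 arrays, was itself written after the largest changes on these arrays had been seen and so decides nothing. In the split of the siRNA 1 and siRNA 2 arrays 14534 genes were called, against 0 with limma in the highest of the other 9 splits, and 1 of 10 splits is too few for a share under 0.05.

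The second pattern is the lower androgen-induced list with BD136. Smaller ratios with BD136 stay open (SD 0.415 to 0.424, control 0.458 to 0.464). A rise of 1 DHT-raised list, sterol genes (0.411, SE 0.0962 over 24 members), cannot exclude them. Slide cannot be told apart from the compound, as 0 slides held both. A lower androgen response with BD136 remains a candidate explanation, untested on cells without androgen.

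The third pattern is the 7 genes called with both ASH2L and MEN1 hairpins in LNCaP. Of these, 71.4% had hairpin arrays near 0 and a control array at least 1 from 0, so the lone control array may carry the difference. The same share, 71.4%, differed by over 1 between the scans of that array, against 17 of 25098 genes tested, which is consistent with a fault of the second scan for these genes, TTC17, SUMO1P1 and CYP2F1 among them. An androgen response lost with knockdown stays open, with 64.3% of values in the VCaP control groups sharing the sign of the LNCaP control array. PIP, at 3.06 on the hairpin arrays against -0.090 on the control array, read -0.12 and -0.060 on its scans.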

How the results depend on the processing

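The tests of each ASH2L siRNA alone or against its own ethanol channel, with slide as a fixed block or within the other scan batch, and of gene sets from other experiments with an estimated correlation or without the siRNA controls were chosen after the data had been seen. Over all alternatives 139 counts of called genes stayed within 1.5 times their value, 31 moved further and 12 were 0. The androgen-induced list kept its direction and its side of the threshold (camera's unadjusted p here) in 76 values, lost the call in 10, gained it in 1 and turned in 7. Of the values of named single genes 9613 kept direction and side, 554 lost and 39 gained a call, and 78 turned. Probes near background carry the least certain ratios. Except where stated, the cause was not tested.

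With no background correction, calls numbered 2582 for the LNCaP androgen response, 63 for MEN1 hairpins and 75 for MLL1 hairpins. The sign turned for KLK3 with ASH2L siRNA (0.017), for SUMO1P1 with ASH2L (0.036) and MEN1 hairpins (0.10) in LNCaP, and with ASH2L hairpins in VCaP for MEN1 (-0.014), DSTYK (-1.91) and ZNF701 (-1.74). Among calls with ASH2L hairpins in LNCaP, 66.7% were higher, from 42.9%.

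Median centring in place of loess shifted the median of all genes by -0.264 to 0.191, and values turned here are relative to that shift. Of 65 list calls 10 turned in their median, 18 shrank and 19 grew by over 1.5 times. Calls numbered 6001 for BD136, 12782 for the LNCaP androgen response, 11030 for MEN1 hairpins and 11 for MLL1 hairpins. The share of calls that were higher became 33.1% for the R1881 response with non-targeting siRNA (from 46.8%), 41.0% for ASH2L siRNA (54.0%), 70.8% for siRNA 1 against siRNA 2 (47.5%), 73.4% for DHT with the control compound (49.2%), 15.0% for BD136 (51.9%) and 16.1% for MEN1 hairpins (51.3%). It became 18.5% for R1881 (44.1%) and 19.8% for DHT (43.9%) on VCaP GIPZ arrays, 81.3% for ASH2L hairpins in VCaP (35%) and 36.4% for MLL1 hairpins (50%). The androgen-induced list turned with ASH2L hairpins in VCaP (0.11), as did KMT2A (0.20), TMPRSS2 (0.038) and FKBP5 (0.076). Between the siRNAs KDM6A (0.045), CHGA (0.13), CHGB (0.48), CDKN1A (0.14) and FBL (0.0013) turned. With the control compound ASH2L (0.39), MEN1 (0.12), KMT2A (0.15) and CDKN2C (0.065) turned, and with BD136 MEN1 (-0.18). In the LNCaP response to DHT the values were MEN1 0.26, KMT2A 0.33, KLK3 0.65, HOXB13 0.028, NOP56 0.079 and NOP16 0.045. KMT2A stood at -0.24 with ASH2L hairpins in LNCaP and ASH2L at -0.55 with MEN1 hairpins, and PAGR1 (-0.17) turned in the VCaP GIPZ response to DHT.

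With the Feature Extraction ratio, calls numbered 1089 for BD136 and 15 for ASH2L hairpins in VCaP (20% higher). With limma they numbered 0 for ASH2L hairpins (1758 at an unadjusted p under 0.05) and 0 for MEN1 hairpins (3455) in LNCaP and 0 for MLL1 hairpins (1943). The androgen-induced list stood at 0.0087 with ASH2L siRNA and no longer passed with MLL1 hairpins (-0.082). KLK3 turned with ASH2L siRNA (0.075), DHT with the control compound (-0.011), R1881 (0.035) and DHT (0.034) on VCaP GIPZ arrays and ASH2L hairpins in VCaP (-0.0074). So did KMT2A (0.023) and SNAI2 (-0.42) with BD136, ASH2L in the LNCaP response (-0.031), SUMO1P1 with ASH2L (0.54) and MEN1 hairpins (0.60), and DSTYK (-2.31) and ZNF701 (-2.43) with ASH2L hairpins in VCaP. With the authors' processed values the counts were 1806 for BD136, 145 for MEN1 hairpins, 832 for ASH2L hairpins in VCaP, and 0 by limma for MLL1 hairpins (2080 at an unadjusted p under 0.05), and MEN1 (-0.0082) and KLK3 (-0.011) turned with ASH2L hairpins in VCaP.

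Without a filter on dim probes MLL1 hairpins called 24 genes. With signal above background in both channels on every array, which tests fewer genes, MEN1 hairpins called 19, and the androgen-induced list stood at 0.010 with ASH2L siRNA and no longer passed with ASH2L hairpins in VCaP (-0.17). With the mean over probes, calls numbered 7 for MEN1 hairpins and, by limma, 0 for ASH2L hairpins in LNCaP (860 at an unadjusted p under 0.05), and the list with MEN1 hairpins no longer passed (-0.10). KLK3, whose probes disagree, turned to -0.0011 with R1881 and non-targeting siRNA, 0.91 with ASH2L siRNA, 1.19 between the siRNAs, 1.105, 0.46 and 0.53 for DHT, ASH2L and MEN1 hairpins in LNCaP, 1.11 and 1.16 for R1881 and DHT on VCaP GIPZ arrays, and -0.11 and -0.11 for ASH2L and MLL1 hairpins. ERG with ASH2L siRNA (0.40), FKBP5 with MEN1 hairpins (0.033), KMT2A with ASH2L hairpins in VCaP (0.020) and MEN1 with DHT on the VCaP GIPZ array (0.080) turned too.

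All 23 arrays in 1 fit called 3925 genes in the LNCaP response, 114 with ASH2L and 1371 with MEN1 hairpins there, and 192 with MLL1 hairpins. With the first scans, limma called 0 genes for ASH2L hairpins in LNCaP (890 at an unadjusted p under 0.05). TTC17 (-0.038) turned in the androgen response, CYP2F1 (-0.017) with ASH2L hairpins, and SUMO1P1 (0.017) with MEN1 hairpins. With the second scans the counts were 12 and 123, the androgen-induced list no longer passed (-0.072 and -0.11), and MEN1 in the response (0.018) and KLK3 with MEN1 hairpins (0.021) turned. With scan batch or slide as a fixed block and within the control arrays' batch, the list with ASH2L siRNA stood at 0.020 and KLK3 at 0.056. With siRNA 1 alone the list stood at 0.35 and ERG at 0.46, and with siRNA 2 alone the list passed at -0.19, with KMT2A at 1.15 and KLK3 at 0.49.

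With an estimated correlation the androgen-induced list no longer passed with ASH2L (-0.22, p = 0.0609) and MEN1 hairpins in LNCaP (-0.20, p = 0.246) or ASH2L (-0.17, p = 0.099) and MLL1 hairpins in VCaP (-0.079, p = 0.0696). Among 65 list calls 1 held. Genes induced in another experiment no longer passed with ASH2L siRNA (-0.21) and ASH2L hairpins in VCaP (-0.16). As Spearman correlations, effects agreed at 0.0016 for ASH2L siRNA and MLL1 hairpins, 0.15 and 0.18 for BD136 with LNCaP ASH2L and with MLL1 hairpins, and 0.30 for the LNCaP hairpins.

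The replicate numbers did not pair the arrays. Deviations of same-numbered arrays correlated at -0.0279 to 0.0986 in the siRNA experiment and -0.0276 in the drug experiment. With the replicate block the counts were 16154, 15099, 14584, 12088 and 2612, for R1881, ASH2L siRNA, the difference of the siRNAs, DHT and BD136, and KLK3 with ASH2L siRNA turned (0.031).

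Leaving out 1 array at a time gave 0 to 6741 calls for the LNCaP response, 0 to 131 for ASH2L and 0 to 3670 for MEN1 hairpins there (highest without a MEN1 hairpin array), 47 to 4185 for BD136 (47 without BD136 array 1 and 126 without array 2) and 45 to 269 for MLL1 hairpins (highest without an ASH2L hairpin array), where fewer arrays set the spread. The lowest LNCaP counts, from limma, came without an ASH2L hairpin array, with 270 to 3788 genes at an unadjusted p under 0.05. The list with MEN1 hairpins stood at -0.20 to -0.088, lowest in size without MEN1 hairpin array 2. KLK3 ranged over -0.030 to 0.024 with ASH2L siRNA, -0.056 to 0.081 with ASH2L and -0.023 to 0.21 with MLL1 hairpins in VCaP. MEN1 ranged over -0.022 to 0.049 with BD136 and -0.089 to 0.021 in LNCaP and -0.072 to 0.073 in VCaP with ASH2L hairpins. With ASH2L and MEN1 hairpins in LNCaP KMT2A ranged over -0.026 to 0.36 and -0.53 to 0.24, and ASH2L over -0.029 to 0.10 with the latter.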

Other observations

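All tests in this part, of each ASH2L siRNA against the ethanol channel of its own arrays, were chosen after the data had been seen and do not rest on the non-targeting arrays. The ethanol channel held control cells, so effects of the knockdown and of R1881 cannot be told apart in them.

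In siRNA 1 cells with R1881, androgen-induced genes were higher than in control cells with ethanol (median 1.17, adjusted p = 8.06e-16, or adjusted p = 0.0769 with an estimated correlation), and of 50 measured, 43 rose and 2 fell (43 and 2 adjusted over the list alone). Genes of the unfolded protein response were higher (adjusted p = 1.6e-10, or adjusted p = 0.0576 with an estimated correlation), and of 23 measured, 22 rose and 1 fell (22 and 1 adjusted over the list alone). Sterol and lipid synthesis genes were higher (median 1.00, or 0.64 under median centring, adjusted p = 3.59e-11, or adjusted p = 0.0769 with an estimated correlation), and of 24 measured, 23 rose and 1 fell (23 and 1 adjusted over the list alone). Luminal markers were higher (median 0.54, but -0.030 under median centring, adjusted p = 0.000317, or adjusted p = 0.0769 with an estimated correlation), and of 12 measured, 10 rose and 1 fell (10 and 1 adjusted over the list alone). Androgen-repressed genes were lower (adjusted p = 7.67e-05, or adjusted p = 0.0576 with an estimated correlation), and of 13 measured, 1 rose and 11 fell (1 and 11 adjusted over the list alone). Proliferation genes were lower (median -0.92, adjusted p = 5.19e-13, or adjusted p = 0.0173 with an estimated correlation), and of 31 measured, 0 rose and 31 fell (0 and 31 adjusted over the list alone). Genes of MYC and ribosome biogenesis were lower (adjusted p = 4.58e-06, or adjusted p = 0.0329 with an estimated correlation), and of 16 measured, 0 rose and 15 fell (0 and 15 adjusted over the list alone).

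In siRNA 2 cells with R1881, against control cells with ethanol, androgen-induced genes went both ways (median 0.11, or -0.43 under median centring, adjusted p = 0.159), and of 50 measured, 24 rose and 15 fell (24 and 15 adjusted over the list alone). Androgen-repressed genes were lower (adjusted p = 0.00792, or adjusted p = 0.179 with an estimated correlation), and of 13 measured, 0 rose and 10 fell (0 and 10 adjusted over the list alone). Proliferation genes were lower (adjusted p = 2.33e-06, or adjusted p = 0.0664 with an estimated correlation), and of 31 measured, 1 rose and 27 fell (1 and 27 adjusted over the list alone). Sterol and lipid genes had a median of 0.65 (adjusted p = 0.00106, or adjusted p = 0.556 with an estimated correlation), which was -0.56 under median centring, and of 24 measured, 18 rose and 4 fell (18 and 4 adjusted over the list alone). Those of the unfolded protein response had a median of 0.35 (adjusted p = 0.0344, or adjusted p = 0.556 with an estimated correlation), which was -0.59 under median centring, and of 23 measured, 14 rose and 6 fell (14 and 6 adjusted over the list alone). MYC and ribosome biogenesis genes were lower (adjusted p = 0.000368, or adjusted p = 0.0664 with an estimated correlation), and of 16 measured, 1 rose and 13 fell (1 and 13 adjusted over the list alone).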
